A study of Mus musculus with 18 samples.

How the data were processed

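The samples were 18 RNA libraries of mouse cortex: input and HA-immunoprecipitated (IP) RNA of control, tumor and AZD8055-treated tumor mice, 3 libraries for each of 6 groups. Counts of reads per gene symbol were deposited by the authors as a table of 23420 symbols, raw and not normalized. Per the labels the RNA was cleaned with RNeasy Mini columns and libraries were made with the NEBNext Ultra Directional kit, and the submitters' processing notes name STAR, DESeq2 and the mm10 genome. The versions, the counting tool, the annotation and the use of strand are not given in the sources used here. Of the symbols, 21571 (92.1%) were found in a RefSeq table for GRCm38, which also gave the coordinates. Library totals lay between 13561511 and 34178417 counts.

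Groups, comparisons, 28 gene lists and the alternatives were chosen before the data were examined, except where the text says otherwise. Libraries were scaled by TMM, genes were kept by filterByExpr, and differences were tested in edgeR 4.0.16 (quasi-likelihood F test, R 4.3.3) with Benjamini-Hochberg adjustment at 0.05. IP and input were compared within each condition in its own fit, and conditions were compared within each fraction in a fit of its 9 libraries. The difference between changes in IP and in input was a contrast in a fit of all 18 libraries. That made 11 gene-wise comparisons. Neuron-enriched genes were those higher in tumor IP than in tumor input, following the study's plan, and p-values were adjusted again within that set. Genes changed back were those called between tumor and control and called in the opposite direction between AZD and tumor. Errors beside a log2 fold are standard errors from the fit.

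Gene lists were tested with camera in limma 3.58.1 at the preset correlation of 0.01, with camera at an estimated correlation, and with fry. The lists covered markers of excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes, the glioma lineage, microglia, T cells and endothelial cells. Others covered proliferation, ribosomal proteins, other TOP genes, oxidative phosphorylation, immediate-early genes, glutamate synapses, synaptic vesicles, GABA receptors, channels, ATF4 targets, cholesterol synthesis, glycolysis, interferon response, antigen presentation, lysosomes, the mTOR pathway, matrix and neuronal injury. The list of 13 mitochondrially encoded genes had 0 members in the table and the erythrocyte list at most 2 tested, so 26 lists were tested.

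Genes were named by a fixed rule. In each comparison, genes with an adjusted p under 0.05, a mean of at least 10 CPM and no overlap between the groups' libraries were ranked, and the 8 highest and 8 lowest log2 folds could be named (3 and 3 in comparisons of control IP or AZD IP with input, AZD with control, AZD with tumor in input, and the contrasts of IP minus input). Names of the Gm, Rik, -ps and -rs kinds were left out. From each list up to 4 members with the smallest adjusted p and up to 2 that did not pass could be named. Camk2a, Slc17a7, Gad1, Gad2, Aqp4, Gfap, Mbp, Pdgfra, Olig2, Mki67, Top2a, C1qa, C1qb, Cldn5, Rpl22 and Hba-a1 were fixed; Hba-a1 was listed at 0 in every library. A group with 0 counts was set to a floor of 3 counts over the group.

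Whether the same number marks the same mice in input and IP was checked by correlating, across 11889 genes, each library's deviation from its group. Same-number input and IP libraries correlated at 0.32 to 0.38 in control, 0.67 to 0.89 in tumor and 0.30 to 0.63 with AZD, and each library matched its own number best. The unpaired fit was kept as planned, and a fit with the replicate number as a block was run as an alternative.

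The tests were tested on simulated data with 200 changed genes. At a log2 change of 1, the share found was 41.8% for tumor IP against input, 98.5% for control IP against input, 79.1% for AZD IP against input, 82.1% for tumor against control in IP, 86.6% for AZD against tumor in IP and 79.1% for AZD against control in IP. In input it was 76.1% for tumor against control, 68.7% for AZD against tumor and 67.2% for AZD against control, and for IP minus input 61.2% (tumor) and 52.2% (AZD). False calls numbered 6 to 17 per comparison. The median standard error was 0.11 for control IP against input and 0.24 for the contrasts of IP minus input. Camera called the 1 changed list of 30 simulated and 0 of the others. The simulated genes were drawn independently, so this does not check camera on lists of correlated genes. In tumor against control in IP, the 19 lists called only at the preset correlation had estimated correlations of 0.166 to 0.761.

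The alternatives were DESeq2 1.42.0, other scalings, a mean of at least 5 CPM, the replicate block, all 18 libraries in a single fit, leaving out each replicate, and other definitions of the neuron-enriched set. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.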

Results

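RNA was sequenced from the cortex of mice that carry an HA tag on the ribosomal protein Rpl22 in cells expressing Camk2a-Cre, a recombinase active in forebrain excitatory neurons. Polysomes pulled down through the tag gave the IP (immunoprecipitated) fraction, and the unfractionated RNA gave the input. The 3 conditions were control mice without tumor, mice with implanted glioma cells (tumor), and tumor mice treated with AZD8055, an ATP-competitive inhibitor of the mTOR kinase (AZD). Each of the 6 groups of condition and fraction held 3 libraries, 18 in all. Total counts lay between 15300374 and 17839717 in control input and between 23097718 and 34178417 in control IP. They lay between 17853365 and 23448015 in tumor input, 16673120 and 31561226 in tumor IP, 14735054 and 19742504 in AZD input, and 13561511 and 31052149 in AZD IP. The highest share of a library taken by any gene was 2.26% (Malat1 in AZD input replicate 2). The labels speak of groups of mice and do not say that each number is a separate animal, so the p-values measure the spread between these libraries, which may be partly technical. The library names fall into 3 sets: PD013 holds the control and tumor input, PD015 the control and tumor IP, and PD028 all AZD libraries. Tumor against control within a fraction, and AZD IP against AZD input, lie within a library set. In the contrast of IP minus input between tumor and control the difference between PD013 and PD015 is common to both conditions. In the other comparisons the library set changes with the group, and the effects of both cannot be told apart. In a principal component analysis of all libraries the first axis took 55.5% of the variance and the second 21.2%. On the first axis the tumor input libraries lay at 78.9, 48.1 and 47.6 the AZD IP libraries at -40.7, -54.5 and -47.9, and the control IP libraries at -50.4, -47.7 and -48.6. On the second axis AZD IP lay at 53.9, 49.6 and 37.3 and control IP at -1.2, -16.7 and -14.6.

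The first question was which RNA the IP enriched over input in each condition. Camk2a, the kinase gene whose promoter drives Cre (chromosome 18, 60925307 to 60988152, GRCm38), was measured at 1061 ± 186 CPM (counts scaled to library size, mean ± SD, n = 3 here and below) in control input and 1597 ± 80.5 in control IP. In tumor it was at 452 ± 251 in input and 725 ± 121 in IP, and with AZD at 676 ± 182 and 1502 ± 535. Slc17a7, the vesicular glutamate transporter of excitatory neurons, was at 889 ± 114 and 862 ± 128 CPM in control input and IP, 588 ± 134 and 624 ± 97.1 in tumor, and 556 ± 1.41 and 1185 ± 170 with AZD. Genes of other cells were depleted from the IP with AZD far more than in the other conditions. Gad1, which makes GABA in inhibitory neurons, went from 440 ± 28.8 CPM in control input to 407 ± 36.6 in control IP and from 286 ± 44.6 to 255 ± 62.5 in tumor. With AZD it went from 322 ± 41.0 to 77.4 ± 28.7, and Gad2 from 371 ± 91.4 to 140 ± 77.8. Aqp4, the astrocyte water channel, stood at 171 ± 8.37 and 155 ± 13.0 CPM in control, 318 ± 76.4 and 284 ± 55.8 in tumor, and 242 ± 14.7 and 42.4 ± 2.93 with AZD. The myelin gene Mbp fell from 608 ± 94.5 to 187 ± 50.3 CPM between AZD input and AZD IP. In control it went from 1181 ± 66.5 to 832 ± 155, and in tumor from 552 ± 260 to 389 ± 174. The complement gene C1qa of microglia stood at 25.2 ± 1.17 and 28.7 ± 4.82 CPM in control input and IP, 30.5 ± 6.56 and 33.3 ± 1.43 in tumor, and 42.7 ± 5.06 and 6.22 ± 1.54 with AZD.

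**Figure D1:**
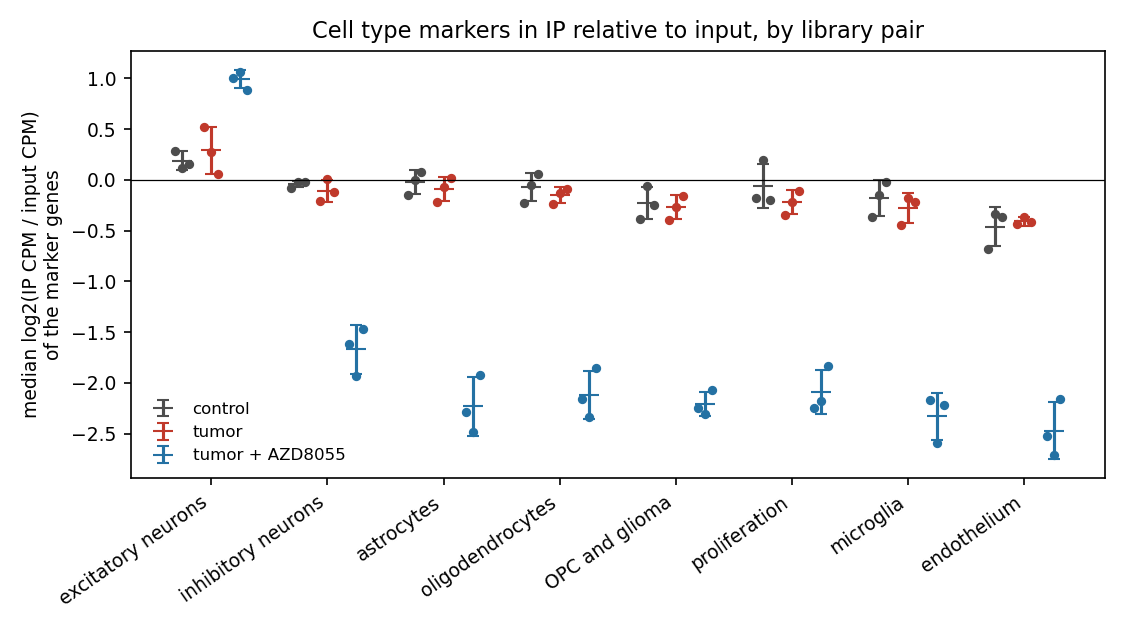
Median log2 ratio of IP over input (vertical axis) for lists of cell-type marker genes, by condition; points are the 3 numbered pairs of libraries and bars the mean with its SD. The astrocyte list averages -0.02 in control, -0.09 in tumor and -2.23 with AZD, and the excitatory-neuron list 0.19, 0.29 and 0.99.

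Over marker lists fixed in advance, the median log2 ratio of IP over input within numbered pairs was 0.19 ± 0.09 (SD, n = 3) for excitatory-neuron genes in control, 0.29 ± 0.23 in tumor and 0.99 ± 0.09 with AZD. For inhibitory-neuron genes it was -0.04 ± 0.03, -0.11 ± 0.11 and -1.67 ± 0.24, for astrocyte genes -0.02 ± 0.12, -0.09 ± 0.12 and -2.23 ± 0.29, and for endothelial and pericyte genes -0.46 ± 0.19, -0.41 ± 0.04 and -2.47 ± 0.28. The genes of the glioma lineage (oligodendrocyte precursors) stood at -0.23 ± 0.16, -0.27 ± 0.12 and -2.21 ± 0.12. Pdgfra, the receptor that marks that lineage (chromosome 5, 75151322 to 75198206), was at 2872 ± 651 CPM in tumor input and still at 2337 ± 397 in tumor IP, against 1733 ± 384 and 262 ± 47.3 with AZD and 103 ± 25.5 and 89.0 ± 17.0 in control.

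With edgeR (quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05), 2644 genes were higher and 2817 lower in control IP than in control input, of 14958 tested. Camk2a was higher (log2 fold 0.68 ± 0.12 SE, adjusted p = 0.000967), as was Rprm (0.69 ± 0.10), a p53-induced arrest gene used as a layer marker. Otof, a calcium sensor of synaptic exocytosis, was lower (-0.80 ± 0.11). Of 26 excitatory-neuron genes 10 were higher and 2 lower (12 adjusted over the list alone), with 14 not passing, such as Grin2b (0.20 ± 0.08, adjusted p = 0.0763). The 25 endothelial genes gave 0 higher and 17 lower, among them Slco1a4 (-0.95 ± 0.13), a transporter of the blood-brain barrier, and Pdgfrb (-0.65 ± 0.10), and 17 were called adjusted over the list alone. The named genes with the largest falls were Snord15b (-4.61 ± 0.53) and Scarna6 (-3.20 ± 0.30), which guide RNA modification, and the noncoding Mirg (-3.44 ± 0.30). Camera with the preset correlation called 5 of 26 lists (endothelial and ribosomal protein genes lower, presynaptic, oxidative phosphorylation and glycolysis genes higher), and none of the 5 passed with an estimated correlation (adjusted p = 0.93 for each). Without control replicate 3 the count fell from 5461 to 3134 genes.

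In tumor, 322 genes were higher and 454 lower in IP than in input, of 15245 tested. The genes higher included Ppp1r9a (2.08 ± 0.37, neurabin, an actin-binding scaffold of dendritic spines), Myh10 (1.76 ± 0.34, a nonmuscle myosin), Aftph (1.83 ± 0.25, a trafficking protein), Nme7 (2.05 ± 0.15), Gca (2.28 ± 0.32) and Cd163 (2.70 ± 0.31, a macrophage scavenger receptor). Genes lower included Snord15a (-5.69 ± 0.55), Snord17 (-4.41 ± 0.37), Apex1 (-2.26 ± 0.25, a base-excision repair enzyme), Gtf3a (-2.27 ± 0.15) and Lypd1 (-2.29 ± 0.25). Nme7 (2.21), Gca (1.39), Cd163 (2.73), Apex1 (-2.50), Gtf3a (-3.01) and Lypd1 (-2.30) moved in the same direction from tumor input to AZD input, so their change can come from the PD013 set. Bricd5 (chromosome 17, 24473487 to 24475471) had 1347 counts in tumor input and 0 in tumor IP, at least 491-fold lower against a floor of 3 counts over the group, which covers counting error only. It had 0 counts in AZD input and AZD IP too, so its absence was not limited to IP libraries, and its span overlaps Mlst8 (chromosome 17, 24473550 to 24479114). Bricd5 is not among the 3 genes high in PD013 alone by the rule given below, so whether it follows the library set stays open. Cdr1 (chromosome X, 61183246 to 61185558) had 1 count in tumor input and 4974 in tumor IP, a ratio of 4515 with an exact 95% binomial counting interval of 810 to 178362. Klhl34 went from 6 counts to 2641. Cdr1 and Klhl34 are among genes near 0 in every PD013 library and present in the other sets, whatever the fraction. None of the 26 excitatory-neuron genes passed in edgeR (0 adjusted over the list alone), with 1 higher at an unadjusted p under 0.05 and 0 in DESeq2. With the replicate number as a block (paired fit) 14 were higher and 3 lower, the list's adjusted p went from 0.122 to 0.00375 (0.921 with an estimated correlation), and the total rose from 776 to 5433 genes. The 24 glioma-lineage genes gave 0 higher and 3 lower (5 adjusted over the list alone), with Ptprz1 at -0.58 ± 0.10, Sox10 at -0.78 ± 0.15 and Nkx2-2 at -0.65 ± 0.14. Camera with the preset correlation called 6 lists (glioma-lineage, proliferation, endothelial and ribosomal protein genes lower, presynaptic and glycolysis genes higher), and with an estimated correlation the 6 had adjusted p = 0.77 to 0.979. The count of 776 was 0 without tumor replicate 2 (edgeR, 1419 genes at an unadjusted p under 0.05, DESeq2 271), 4 without tumor replicate 3 and 1755 without tumor replicate 1.

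With AZD, 4362 genes were higher and 4883 lower in IP, of 15040. Of 26 excitatory-neuron genes 21 were higher and 1 lower (22 adjusted over the list alone), with a median log2 fold of 0.97 and adjusted p = 1.48e-08 (0.25 with an estimated correlation). They included Neurod2 (1.56 ± 0.13) and Tbr1 (1.51 ± 0.13), transcription factors of cortical projection neurons, and Slc17a7 (1.37 ± 0.12), while Arpp21 did not pass (0.18 ± 0.14). All 24 astrocyte genes were lower (24 adjusted over the list alone, median -2.20), as were all 24 glioma-lineage genes, 28 of 30 proliferation genes, 24 of 27 microglial genes, 23 of 25 endothelial genes, 23 of 24 oligodendrocyte genes and 22 of 24 inhibitory-neuron genes (24, 28, 26, 23, 23 and 23 adjusted over the list alone). Slc1a3, the astrocyte glutamate transporter, was at -2.62 ± 0.15, Olig2 at -2.40 ± 0.12 and Itgam at -2.87 ± 0.16. Synaptic vesicle genes were higher in 34 of 42 cases and lower in 2 (37 adjusted over the list alone), such as Nsf (1.34 ± 0.10) and Vamp2 (1.48 ± 0.12), and mitochondrial respiratory genes in 62 of 75 with 0 lower (64 adjusted over the list alone). The largest increases were Bcar1 (2.72 ± 0.26) and Nedd9 (2.00 ± 0.17), docking proteins of adhesion signalling, and Aftph (1.88 ± 0.11). Camera called 19 lists with the preset correlation and 0 with an estimated correlation (adjusted p = 0.21 to 0.606 for those 19; fry called 20). Scaling to plain totals moved the median of all genes by -0.275, and the mTOR-pathway, lysosome, other TOP (translation factors with a 5' oligopyrimidine tract) and immediate-early lists change sign with it, so no direction is given for them here. Without AZD replicate 2 the count of 9245 fell to 5929.

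The next question was what the tumor changed in the IP RNA, against the same comparison in input. Of 15734 genes, 4108 were higher and 3294 lower in tumor IP than in control IP. Cdk1, the mitotic kinase, was higher by 5.67 ± 0.30 (adjusted p = 2.9e-07), Cdkn2a, a cell-cycle inhibitor gene, by 6.36 ± 0.60, Pbk, a mitotic kinase, by 5.54 ± 0.50, and the homeobox gene Meox1 by 6.65 ± 0.34. All 24 glioma-lineage genes were higher (24 adjusted over the list alone), with a median of 3.42: Cspg4 (NG2) by 4.52 ± 0.14, Olig2 by 3.63 ± 0.15 and Olig1 by 3.34 ± 0.14. Olig2 was at 15.8 ± 1.05 CPM in control IP, 207 ± 27.0 in tumor IP and 242 ± 18.3 in tumor input. All 30 proliferation genes were higher (30 adjusted over the list alone, median 3.80), and Mki67 stood at 6.45 ± 1.27 CPM in control IP and 189 ± 16.6 in tumor IP. Matrix genes were higher in 21 of 29 cases and lower in 1 (23 adjusted over the list alone), such as Vcan (3.85 ± 0.31) and Lama4 (2.46 ± 0.10). Gfap was higher by 2.22 ± 0.34. Of the microglial list 4 of 28 microglial genes were higher and 1 lower (4 adjusted over the list alone; Spp1 1.36 ± 0.37), with a median of 0.20 and a camera direction of down (adjusted p = 0.888).

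Neuronal genes were lower in tumor IP. Of 26 excitatory-neuron genes 20 were lower and 1 higher (22 adjusted over the list alone), with a median of -0.82 and adjusted p = 2.47e-05 (0.461 with an estimated correlation). Nrgn, a calmodulin-binding protein of dendritic spines, was at -1.14 ± 0.13, the NMDA receptor subunit Grin2b at -1.16 ± 0.17, and Sulf2, a sulfatase that glioma cells also express, at 2.15 ± 0.13. Synaptic vesicle genes were lower in 41 of 42 cases (41 adjusted over the list alone, median -0.86), among them Vamp2 (-1.05 ± 0.15), Sv2a (-0.89 ± 0.12) and Syngr1 (-0.83 ± 0.11), and Nrxn2 did not pass (0.03 ± 0.12). Ion-channel genes were lower in 41 of 47 cases and higher in 1 (43 adjusted over the list alone; Kcnj6 -0.93 ± 0.10). Glutamate-synapse genes were lower in 30 of 41 and higher in 3 (35; Gria1 -0.87 ± 0.09, Gria4 1.16 ± 0.08), and GABA-receptor genes lower in 14 of 20 and higher in 2 (17; Gabrb1 -0.87 ± 0.11). The inhibitory-neuron list moved with them, with 14 of 25 lower and 1 higher (16 adjusted over the list alone; Pvalb -1.35 ± 0.30), as did oligodendrocyte genes (13 of 24 lower, 1 higher, 14 adjusted over the list alone; Mog -1.24 ± 0.30) and astrocyte genes (14 of 24 lower, 3 higher, 20 adjusted over the list alone; Aldh1l1 -0.79 ± 0.13). The genes with the largest falls by the fixed rule were Baiap3 (-2.23 ± 0.29, a dense-core vesicle protein), Htr1a (-1.60 ± 0.29), Grm2 (-1.48 ± 0.28), Lamp5 (-1.46 ± 0.45), the neurofilament gene Nefm (-1.45 ± 0.28) and the calcium sensor Syt2 (-1.44 ± 0.33), with no overlap between tumor and control libraries, which chance gives for 10% of genes at 3 against 3.

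Several stress, immune and growth lists were higher in tumor IP at the preset correlation, and none of them passed with an estimated correlation (adjusted p = 0.461 to 0.598). Targets of ATF4, the transcription factor of the integrated stress response, were higher in 25 of 29 cases with 0 lower (28 adjusted over the list alone, median 1.17), such as Mthfd2 (2.20 ± 0.20), Slc7a5 (1.88 ± 0.17) and Psat1 (1.26 ± 0.11), while Ddit3 did not pass (0.34 ± 0.15). Interferon-response genes were higher in 23 of 28 (23 adjusted over the list alone, median 1.44; Rtp4 3.03 ± 0.31, Ifit2 1.67 ± 0.12), and antigen-presentation genes in 11 of 17 (12; Tap1 1.63 ± 0.29). Ribosomal protein genes were higher in 71 of 77 (74 adjusted over the list alone, median 0.69; Rpl13 1.43 ± 0.14), and other TOP genes in 22 of 30 with 1 lower (25; Pabpc1 0.89 ± 0.09). Rpl22 itself, the tagged protein's gene, was at 49.4 ± 2.04 CPM in control IP and 147 ± 41.8 in tumor IP, and at 54.4 ± 7.02 and 151 ± 46.6 in the inputs. Immediate-early genes, which neurons switch on when active, were higher in 16 of 32 with 0 lower (16 adjusted over the list alone): Trib1 by 3.31 ± 0.26, Dusp6 by 1.92 ± 0.21, Nr4a1 by 2.17 ± 0.32 and Jun by 1.28 ± 0.17, while Bdnf (0.50 ± 0.21, adjusted p = 0.0765) did not pass. Cholesterol-synthesis genes were higher in 12 of 24 (14; Sqle 1.20 ± 0.16), and glycolysis genes lower in 16 of 25 and higher in 3 (21; Gapdh -0.79 ± 0.11, Adm 3.53 ± 0.52). Neuronal-injury genes gave 11 higher and 3 lower of 22 (15 adjusted over the list alone; adjusted p = 0.0903), mTOR-pathway genes 12 higher and 10 lower of 43 (23), and lysosome genes 8 and 11 of 40 (19). Respiratory genes gave 2 and 10 of 75 (6), endothelial genes 1 and 4 of 25 (2), and T cell genes 1 and 2 of 7 (3), the last including Thy1, which neurons also express.

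Camera with the preset correlation called 20 of 26 lists between tumor and control IP. With an estimated correlation only the glioma-lineage list passed (adjusted p = 0.000697), and the 19 others had adjusted p = 0.238 to 0.652. The lists share members: 6 of the 24 glioma-lineage genes, 5 of the 29 matrix genes and 3 of the 26 excitatory-neuron genes sit in another list. The input moved in the same way, with 3798 genes higher and 3663 lower of 15511. There the glioma-lineage median was 3.30 with all 24 genes higher (24 adjusted over the list alone), the excitatory-neuron median -0.93 with 22 of 26 lower and 1 higher (25), the synaptic vesicle median -0.91 with 40 of 42 lower (41), and 26 of 29 ATF4 targets were higher and 1 lower (27). Of the 7371 genes called in IP and tested in input, 7308 (99.1%) had the same sign in input, and 6042 were called in both with the same sign. Across 15269 genes, which are not independent replicates, the IP folds correlated with the input folds at r = 0.931, with a slope of 0.853. Camera called 20 lists in input too, of which 1 passed with an estimated correlation (the glioma-lineage list, adjusted p = 0.00699; the 19 others 0.327 to 0.623). Among the genes with the largest changes in input were Hmga2 (6.32 ± 1.00, a chromatin protein of embryonic and tumor cells), Ccnb1 (5.82 ± 0.53, a mitotic cyclin) and Baiap3 (-2.43 ± 0.29).

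**Figure D2:**
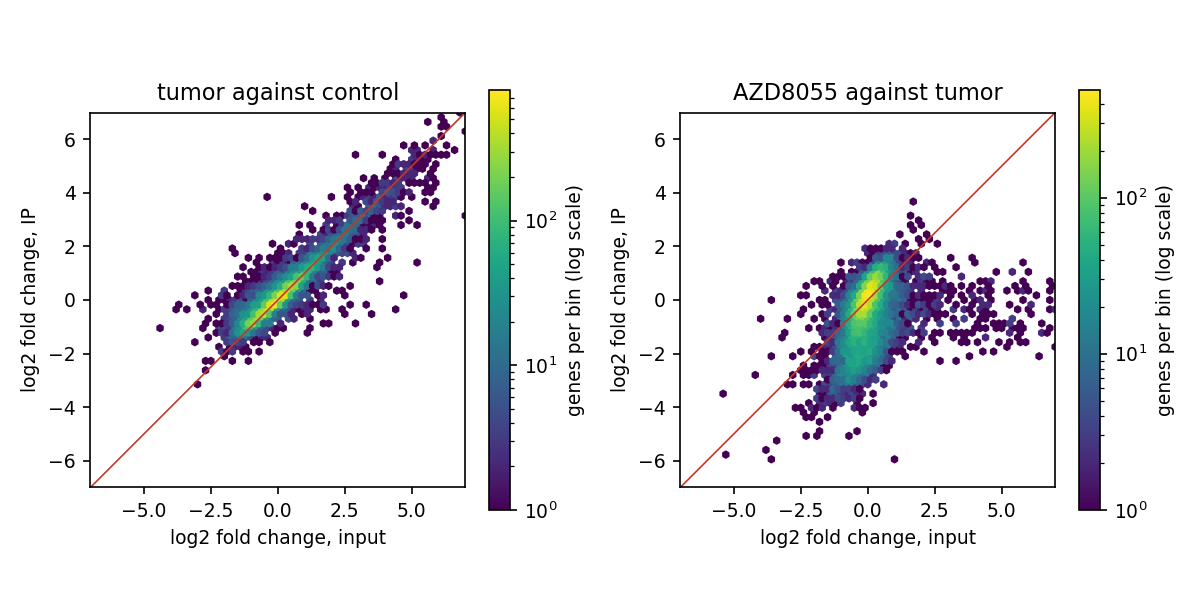
Log2 fold change in IP (vertical axis) against that in input (horizontal axis), for tumor vs control and for AZD vs tumor, with axes from -7 to 7. Genes are binned, the color gives the number of genes per bin (log scale), and the line marks equal folds. The slope is 0.853 for tumor vs control and 0.379 for AZD vs tumor.

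The test of whether the tumor changed IP and input RNA differently (all 18 libraries) called 8 genes higher and 3 lower of 16016 (edgeR; 528 at an unadjusted p under 0.05, 40 in DESeq2). Myh9, a nonmuscle myosin heavy chain (chromosome 15, 77760585 to 77842175), differed by 1.95 ± 0.20 (adjusted p = 0.000211): its log2 ratio of IP over input was -0.39 ± 0.07 (SD, n = 3) in control and 1.57 ± 0.39 in tumor. Gtl3 differed by 1.88 ± 0.19, Limch1, an activator of nonmuscle myosin, by 1.58 ± 0.22, and Ccdc167 by -0.76 ± 0.12. The spectrin gene Sptan1 (1.57), the dystonin gene Dst (1.57), the nuclear-envelope gene Syne2 (1.28), the motor gene Myo5a (1.02) and Rgl2 (0.98) were the others higher, and 9530082P21Rik and 2700099C18Rik the others lower. 9530082P21Rik is among the 29 genes low in PD013 described below. These genes were chosen after their values were seen. Among 26 excitatory-neuron genes 0 passed (edgeR; 1 at an unadjusted p under 0.05, 0 in DESeq2), and the list's median was 0.06. The count of 11 was 67 with the pairs as a block (51 higher, 16 lower) and 21 without tumor replicate 1. It was 4, 3 and 5 without control replicates 1, 2 and 3, 6 and 4 without tumor replicates 2 and 3, and 6 without AZD replicate 2. Camera with the preset correlation called 4 lists (respiratory, cholesterol and neuronal-injury genes lower, ribosomal protein genes higher; medians -0.12, -0.20, -0.09 and 0.08), each with adjusted p = 0.985 with an estimated correlation.

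The study restricted the comparison of conditions to genes enriched in tumor IP over tumor input, here the 322 genes called higher. That set was chosen on the same tumor IP libraries, so its test is not independent evidence. From the fixed lists it held 0 of the 26 excitatory-neuron markers and 0 markers of other cell types, but the macrophage receptor gene Cd163, in no list, is in it. All 29 genes low in PD013 are in it too. In the fit with the replicate number as a block, 2676 genes were higher in tumor IP, among them 14 of the 26 excitatory-neuron markers (3 were lower). The absence of these markers from the set thus depends on the unpaired fit. Of the 322 genes 245 were also higher in control IP over input, against 48.2 expected by chance, and 129 with AZD, against 91.9. Control and tumor IP over input both set PD015 against PD013, and the 245 include the same 29 genes, so their overlap can come from the library sets. Adjusted over the set, 43 of the 322 were higher and 62 lower in tumor IP than in control IP (112 in all when adjusted over all genes). Among the highest were Myh9 (2.76 ± 0.12), Mpzl1 (2.37 ± 0.16), the giant nuclear-envelope protein gene Syne2 (1.76 ± 0.10), Myh14 (1.64 ± 0.20), the oxidative-stress factor Nfe2l2 (1.60 ± 0.17), Limch1 (1.59 ± 0.18) and Pprc1 (1.47 ± 0.16). The lowest included the neuronal factor Bhlhe22 (-0.85 ± 0.11), the 14-3-3 genes Ywhah (-0.78 ± 0.11) and Ywhag (-0.75 ± 0.14), Gca (-0.84 ± 0.20) and Nudt18 (-0.70 ± 0.15), and also Hipk4 (-1.21 ± 0.32), Klhl34 (-0.91 ± 0.18) and BC049635 (-0.78 ± 0.23), which are among the 29 genes low in PD013. The count of 105 was 1500 with the replicate block (386 higher, 1114 lower), 358 without tumor IP replicate 1, 2 without tumor IP replicate 3 and 0 without tumor IP replicate 2, where edgeR left no gene in the set. With the 2644 genes enriched in control IP as the set, 465 were higher and 932 lower.

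The question behind the AZD libraries was whether mTOR inhibition reversed the changes seen with tumor. Between AZD IP and tumor IP 3954 genes were higher and 5275 lower of 15734, a comparison that crosses the library sets PD015 and PD028. Gpr17, a receptor of immature oligodendrocytes, was at -4.25 ± 0.29 (adjusted p = 1.1e-06), the endothelin receptor Ednrb at -3.86 ± 0.13, Olig1 at -3.77 ± 0.15 and Moxd1 at -4.07 ± 0.33. All 24 glioma-lineage genes were lower (24 adjusted over the list alone, median -2.99) and all 30 proliferation genes (30, median -2.22; Mcm3 -3.62 ± 0.32). Pdgfra fell from 2337 ± 397 to 262 ± 47.3 CPM, Olig2 from 207 ± 27.0 to 17.7 ± 2.93, Mki67 from 189 ± 16.6 to 35.5 ± 21.2 and Top2a from 221 ± 8.15 to 24.2 ± 14.8. The markers of every other cell type with a called list moved with them. Astrocyte genes were lower in 23 of 24 cases (24 adjusted over the list alone, median -1.89; Aqp4 -2.61 ± 0.12), and oligodendrocyte genes in 23 of 24 (23; Cnp -2.47 ± 0.18). Microglial genes were lower in 25 of 28 (25, median -2.16; Itgam -2.82 ± 0.15), endothelial genes in 23 of 25 with 1 higher (24; Kdr -2.56 ± 0.19) and inhibitory-neuron genes in 19 of 25 with 1 higher (20, median -1.25). Cldn5, the tight-junction gene of vessels, was at 20.8 ± 2.56 CPM in tumor IP and 4.40 ± 2.12 in AZD IP.

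Excitatory-neuron and synaptic genes were higher with AZD. Of 26 excitatory-neuron genes 19 were higher and 1 lower (21 adjusted over the list alone), with a median of 1.06 and adjusted p = 3.61e-06 (0.281 with an estimated correlation): Nrgn by 1.42 ± 0.13, the calcium-activated kinase gene Ptk2b by 1.25 ± 0.14 and the synaptic zinc transporter Slc30a3 by 1.48 ± 0.19, with Sulf2 at -1.98 ± 0.13 and Otof (1.10 ± 0.54, adjusted p = 0.101) not passing. Synaptic vesicle genes were higher in 37 of 42 cases and lower in 1 (38 adjusted over the list alone, median 1.00). They included Nsf (1.29 ± 0.12), Syp (1.30 ± 0.13) and Sv2b (1.35 ± 0.13), while Bsn did not pass (0.27 ± 0.25). Stx1a, a SNARE of vesicle fusion, was higher by 1.84 ± 0.29 and the synuclein gene Sncb by 1.71 ± 0.22. Channel genes were higher in 32 of 47 and lower in 1 (33, median 0.71; Cacna2d1 1.22 ± 0.13), glutamate-synapse genes in 28 of 41 with 4 lower (33, median 0.61; Gria1 0.84 ± 0.09, Homer3 -2.46 ± 0.27). GABA-receptor genes were higher in 14 of 20 with 3 lower (18, median 0.76; Gabra5 1.06 ± 0.10), and respiratory genes in 63 of 75 with 1 lower (64, median 0.53; Uqcr10 1.03 ± 0.10). Glycolysis genes were higher in 15 of 25 with 5 lower (22, median 0.69; Tpi1 1.30 ± 0.13, Vegfa -2.22 ± 0.23).

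The ATF4, interferon, matrix and cholesterol lists, higher in tumor IP, were lower with AZD at the preset correlation (adjusted p = 0.281 to 0.435 with an estimated correlation). ATF4 targets were lower in 28 of 29 cases with 0 higher (28 adjusted over the list alone, median -1.79), among them Phgdh (-3.47 ± 0.18) and Psat1 (-2.33 ± 0.12) of serine synthesis, and Asns did not pass (-0.12 ± 0.19). Interferon-response genes were lower in 26 of 28 (26, median -1.77; Ifit2 -1.59 ± 0.12), and matrix genes in 26 of 29 with 1 higher (28, median -2.23; Bcan -3.20 ± 0.16). Antigen-presentation genes were lower in 8 of 17 with 1 higher (9; H2-K1 -2.21 ± 0.28) and cholesterol-synthesis genes in 16 of 24 with 2 higher (19, median -0.67; Sqle -1.73 ± 0.17). Immediate-early genes were lower in 18 of 32 with 0 higher (18 adjusted over the list alone, adjusted p = 0.0761), such as Fosl2 (-1.52 ± 0.16) and Klf4 (-2.43 ± 0.38). Ribosomal protein genes did not move together, with 7 higher and 21 lower of 77 (14 adjusted over the list alone), a median of -0.15 and a camera direction of up (adjusted p = 0.877). Rpl13 was at -0.88 ± 0.14 and Rpl38 at 0.74 ± 0.14. The mTOR-pathway list gave 13 higher and 11 lower of 43 (24; adjusted p = 0.529), with Irs1 at -0.84 ± 0.10. Camera called 18 lists with the preset correlation, of which the glioma-lineage list passed with an estimated correlation (adjusted p = 0.008) and the 17 others had adjusted p = 0.281 to 0.435. Plain totals would shift the median of all genes by -0.129.

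**Figure D3:**
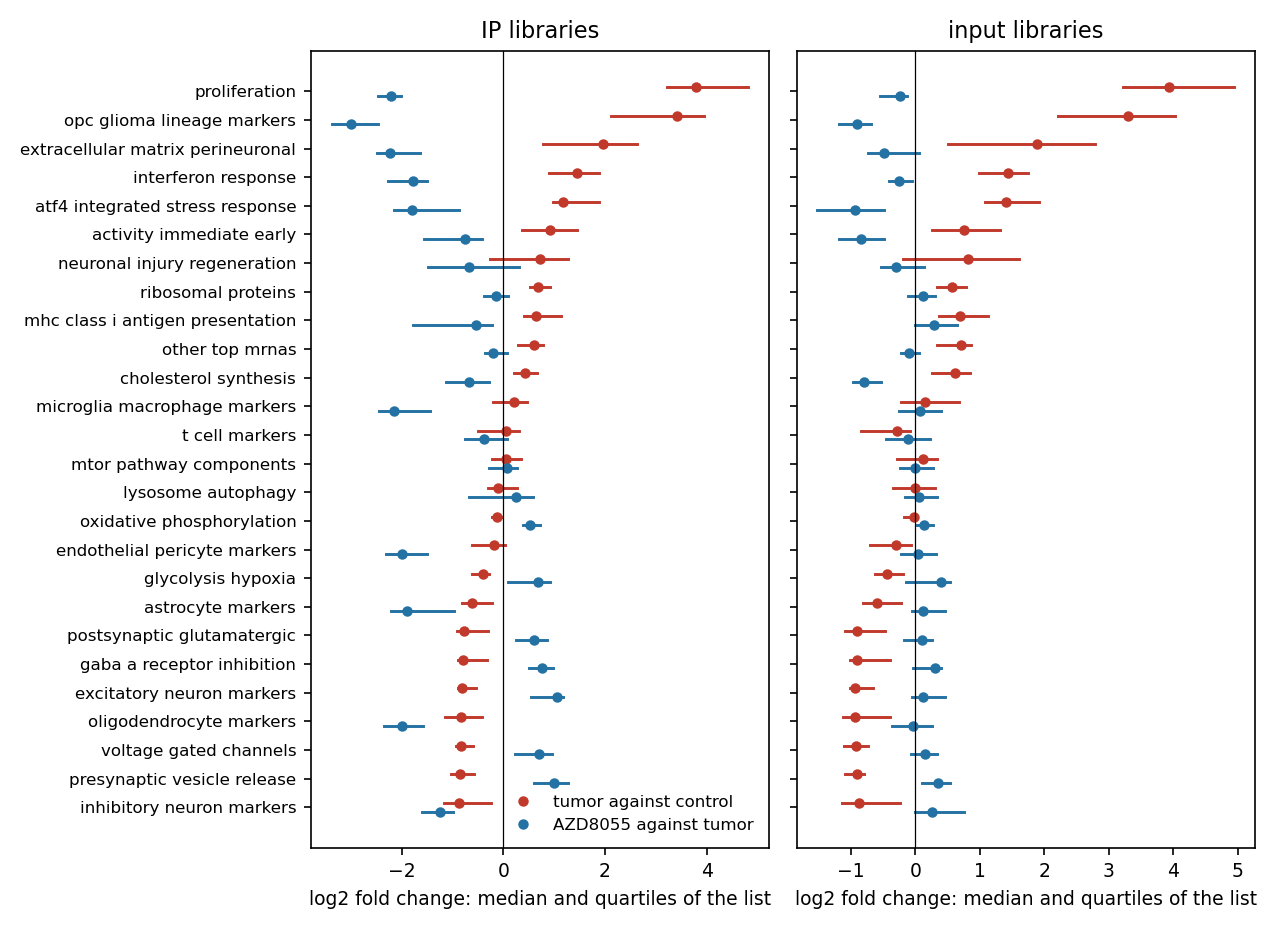
Median log2 fold change (horizontal axis) of each gene list (vertical axis) in the comparisons of conditions, IP and input. In IP the synaptic vesicle list lies at -0.86 for tumor vs control and at 1.00 for AZD vs tumor, and in input at -0.91 and 0.35.

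In input the change with AZD was smaller, with 1224 genes higher and 1422 lower of 15511, again across library sets (PD013 and PD028). The clearest falls were in cholesterol synthesis, ATF4 targets, glioma-lineage genes and immediate-early genes. Cholesterol-synthesis genes were lower in 19 of 24 cases with 0 higher (19 adjusted over the list alone, median -0.79, adjusted p = 4.04e-15, 0.255 with an estimated correlation). Sqle was at -1.54 ± 0.16 and Cyp51 at -1.06 ± 0.11. ATF4 targets were lower in 18 of 29 (23 adjusted over the list alone, median -0.93, adjusted p = 4.12e-11, 0.603 with an estimated correlation), such as the one-carbon enzyme Mthfd2 (-2.23 ± 0.29), Chac1 (-1.65 ± 0.23) and Sesn2 (-1.57 ± 0.26). Glioma-lineage genes were lower in 20 of 24 (24, median -0.90, adjusted p = 4.77e-21, 0.147 with an estimated correlation), with Olig1 at -1.86 ± 0.13 and Gpr17 at -2.39 ± 0.24. Immediate-early genes were lower in 13 of 32 (21, median -0.85, adjusted p = 1.72e-09, 0.3 with an estimated correlation). Egr4 was at -3.25 ± 0.49, Fosl2 at -1.38 ± 0.17, Egr1 at -1.15 ± 0.18 and Nptx2, a synapse-organising pentraxin, at -1.15 ± 0.18. Proliferation genes were lower in 5 of 30 (5, median -0.24), among them Mcm2 (-1.36 ± 0.23), while Mki67 did not pass (-0.70 ± 0.33, adjusted p = 0.171). Synaptic vesicle genes were higher in 8 of 42 (10, median 0.35; Syp 0.86 ± 0.18) and glycolysis genes in 11 of 25 with 1 lower (15; Slc2a1 0.73 ± 0.11). Excitatory-neuron genes gave 0 higher and 1 lower of 26 (0 adjusted over the list alone, adjusted p = 0.329). Camera called 9 lists with the preset correlation and 0 with an estimated correlation (adjusted p = 0.147 to 0.914 for those 9). Bricd5 had 0 counts in AZD input, at least 357-fold lower than in tumor input, but was absent from tumor IP as well, and Gtf3a was at -3.01 ± 0.19. Cdr1 (1 count in tumor input, 4274 in AZD input), Klhl34 (6 and 1564) and Hipk4 (9 and 1060) are genes near 0 in the PD013 set. The count of 2646 was 1359 without AZD Input replicate 3 and 1410 without AZD Input replicate 2.

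The change with AZD differed between IP and input for 5296 genes, 1969 higher and 3327 lower of 16016. Of the genes called between AZD and tumor in IP, 79.9% had the same sign in input, and across genes the folds correlated at r = 0.306 with a slope of 0.379. Astrocyte genes differed downward in 23 of 24 cases (23 adjusted over the list alone, median -2.07; Acsbg1 -2.61 ± 0.20), microglial genes in 23 of 28 (25, median -2.07), glioma-lineage genes in 20 of 24 (23, median -1.83; Olig2 -2.28 ± 0.20) and inhibitory-neuron genes in 16 of 25 (18, median -1.73). Excitatory-neuron genes differed upward in 12 of 26 and downward in 1 (15, median 0.73; Neurod2 1.16 ± 0.22). Of the 18 lists called by camera with the preset correlation, the glioma-lineage, astrocyte and microglial lists passed with an estimated correlation (adjusted p = 0.0177, 0.0217 and 0.0345), and the 15 others had adjusted p = 0.114 to 0.554. With the replicate block the microglial list no longer passed (adjusted p = 0.058 with an estimated correlation). The glioma-lineage, astrocyte, oligodendrocyte, proliferation, endothelial and matrix lists then passed, each at adjusted p = 0.0489. The largest differences belonged to Rell2 (2.88 ± 0.34), Apex1 (2.72 ± 0.28) and Lypd1 (2.46 ± 0.26), and downward to Klhl34 (-7.32 ± 0.49), BC049635 (-8.25 ± 0.80) and Cdr1 (-12.99 ± 0.70), the last 3 near 0 in PD013. Rell2, Apex1 and Lypd1 were high in PD013, with 41.1, 49.9 and 52.1 CPM in tumor input against 8.64, 8.74 and 10.5 in AZD input and 12.7, 10.1 and 9.94 in AZD IP, so their differences follow the library set as well. Cdr1 and BC049635 had 1 count each in tumor input, so their fitted folds depend on the prior count. Plain totals would shift the median by -0.177. The count was 8025 with the pairs as a block and 3498 without AZD replicate 2.

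Against control, AZD IP had 2516 genes higher and 2730 lower of 15734, across PD015 and PD028. Proliferation genes were still higher in 25 of 30 cases with 0 lower (26 adjusted over the list alone, median 1.81, adjusted p = 2.87e-15, 0.431 with an estimated correlation), such as Cenpf (3.33 ± 0.35) and Cdk1 (2.95 ± 0.31). Pnlip (4.27 ± 0.57) and the fibrillin gene Fbn2 (3.34 ± 0.27) were also higher. Astrocyte genes were below control in 23 of 24 (23, median -2.23, adjusted p = 4.08e-48, 0.063 with an estimated correlation), oligodendrocyte genes in 23 of 24 (23, median -2.91), inhibitory-neuron genes in 21 of 25 (23, median -2.21), microglial genes in 20 of 28 (20, median -1.97) and endothelial genes in 22 of 25 (22, median -2.20; Vtn -3.66 ± 0.29). Ribosomal protein genes were higher in 59 of 77 with 0 lower (65 adjusted over the list alone, median 0.55; Rps28 1.51 ± 0.17) and respiratory genes in 49 of 75 with 0 lower (53; Uqcr11 0.74 ± 0.09). Excitatory-neuron genes gave 8 higher and 2 lower of 26 (10 adjusted over the list alone, median 0.26, adjusted p = 0.168) and synaptic vesicle genes 9 and 4 of 42 (13, median 0.05). Unc5b was at -3.46 ± 0.25, and Nptxr, a neuronal pentraxin receptor, at -4.41 ± 0.20, from 38.8 ± 4.41 CPM in control IP to 1.71 ± 0.53 in AZD IP and 0.37 ± 0.27 in AZD input. Camera called 10 lists, none with an estimated correlation (adjusted p = 0.063 to 0.8). The count of 5246 was 3429 without control IP replicate 2.

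In input, AZD against control gave 3214 genes higher and 2489 lower of 15511, across PD013 and PD028. All 30 proliferation genes (30 adjusted over the list alone, median 3.73; Cdc20 4.40 ± 0.32) and 22 of 24 glioma-lineage genes (23, median 1.89; Olig2 2.54 ± 0.14) were higher than in control. Excitatory-neuron genes were lower in 16 of 26 and higher in 1 (19, median -0.62, adjusted p = 0.000185, 0.505 with an estimated correlation; Slc17a7 -0.76 ± 0.16), and channel genes in 34 of 47 with 0 higher (36, median -0.72; Hcn2 -1.14 ± 0.16). Interferon-response genes were higher in 16 of 28 (18, median 1.21; Ifit2 2.18 ± 0.21). Nptxr (-6.53 ± 0.34), Rell2 (-3.27 ± 0.30) and Lypd1 (-2.72 ± 0.19) had the largest falls. Of 14 lists called by camera the glioma-lineage list passed with an estimated correlation (adjusted p = 0.0267), and the 13 others had adjusted p = 0.378 to 0.505. The count of 5703 was 3737 without control Input replicate 2 and 3760 without AZD Input replicate 1.

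Genes that changed with tumor and changed back with AZD in IP numbered 5597, with 3272 higher in tumor and then lower and 2325 lower and then higher. Another 288 went on in the same direction. Those that fell again included Meox1, Cdkn2a, Cdk1, Tecta and Pbk. Those that came back up included the serotonin receptor gene Htr1a, the glutamate receptor gene Grm2, Lamp5, Nefm, Rph3a (-1.42 ± 0.26 with tumor), Sncb (-1.31 ± 0.22) and Cdk5r2 (-1.30 ± 0.21). Of the 5597, 4016 were not called between AZD and control, which does not show that they equal control. Another 443 still differed on the same side and 1138 on the other side, and 5085 had a smaller fold against control than in tumor. The fold of AZD against control is the sum of both folds, so choosing opposite signs favors a smaller fold, which is no separate evidence of a return. Of all 7402 genes called between tumor and control, 6215 had a smaller fold with AZD. The comparisons of tumor with control and of AZD with tumor share the tumor libraries, which pushes their folds to opposite signs. By n1 x n2 / N, 1377 and 828 genes would be expected in each direction. The 20 simulations without any effect gave 0 genes, but tumor vs control calls there averaged 0.55, so that 0 is no reference for the 5597. The covariance of both folds was -0.653, against -0.0419 in the simulations, and the correlation -0.670, against -0.501. Opposite signs were found for 76.5% of all genes, against 66.6% in the simulations. The 3 tumor libraries cannot be split into sets of at least 2, so part of the excess can still come from sharing them. Of the tumor-then-AZD genes, 85.6% of those higher and 85.0% of those lower were called the same way between tumor and control in input. Of all 7371 genes called between tumor and control in IP and tested in input, 6042 were called the same way there. Such calls in input were thus common among all genes changed with tumor. Among the other-cell lists, glioma-lineage and proliferation genes carry the same pattern in IP: glioma-lineage genes went from a median of 3.42 to -2.99. Astrocyte, oligodendrocyte and inhibitory-neuron genes do not, as most were lower in tumor IP and lower again with AZD.

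Within the neuron-enriched set of 322 genes, 80 were higher and 68 lower in AZD IP than in tumor IP (adjusted over the set; 152 in all when adjusted over all genes). Among the highest were Nov (1.45 ± 0.13), Bhlhe22 (1.32 ± 0.11), Ywhah (1.26 ± 0.11), Krt12 (1.20 ± 0.16), Ywhag (1.00 ± 0.14) and Spryd3 (0.95 ± 0.08), and the lowest Nfe2l2 (-3.45 ± 0.19), Myh14 (-3.13 ± 0.22), Myh9 (-3.07 ± 0.12) and Ppp1r9a (-1.76 ± 0.27). Over all genes 9229 of 15734 (58.7%) were called. Changed back within the set were 91 genes. The set was chosen as high in the same tumor IP libraries, which pushes its genes toward lower values with AZD. The comparison also crosses PD015 and PD028, so neither count is independent evidence of a change back in neurons. The count of 148 was 1779 with the replicate block (1290 higher, 489 lower), 451 without tumor IP replicate 1, 2 without tumor IP replicate 3 and 0 without tumor IP replicate 2, where edgeR left no gene in the set.

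Genes low or high in a single library set were counted because Cdr1 and Klhl34 stood out. With a ratio of at least 8 and at least 1 CPM, 29 genes were low and 3 high in PD013, and 0 were low or high in PD015 or PD028 alone. Cdr1 was at 0.042 ± 0.037 CPM in control input, 0.015 ± 0.026 in tumor input, 106 ± 22.9 in control IP, 67.5 ± 19.3 in tumor IP, 83.4 ± 2.74 in AZD input and 28.3 ± 13.6 in AZD IP. Hipk4, a kinase gene, was at 0.058 ± 0.056 and 0.14 ± 0.030 CPM in control and tumor input, against 21.4 ± 7.59 in AZD input.

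**Figure D4:**
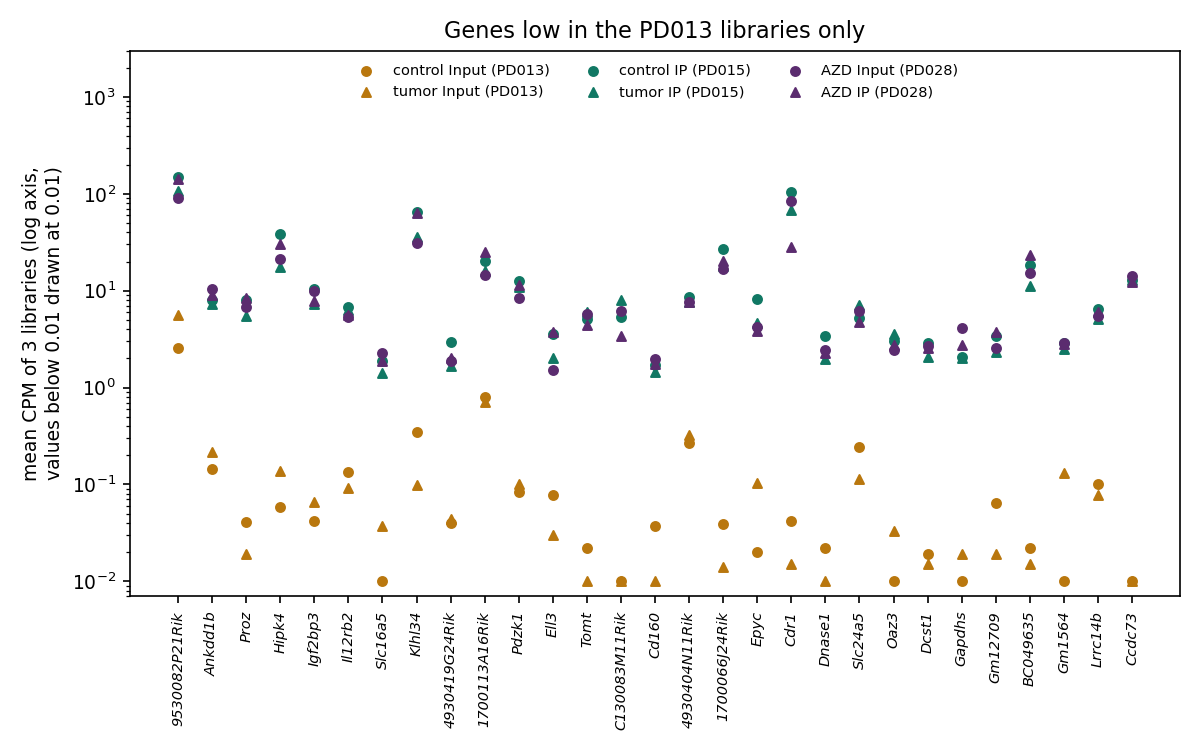
Level in CPM (log scale) of the 29 genes low in the PD013 libraries alone, a point per group (mean of 3 libraries), with values under 0.01 CPM drawn at 0.01. Cdr1 averages 0.042 CPM in control input and 83.4 in AZD input.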

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

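The tests of shared tumor libraries, other-cell RNA, library sets, return of excitatory-neuron transcripts, IP enrichment, change with AZD, a single tumor library pair and tumor-cell RNA in the IP below were chosen only after the result was seen; the others were written before. Results are listed here because a test of the difference between groups' effects called them. The change from control to tumor differed between IP and input for 11 genes, among them Myh9 (1.95), Gtl3 (1.88), Limch1 (1.58) and Ccdc167 (-0.76). The change from tumor to AZD differed for 5296 genes, among them Rell2 (2.88), Apex1 (2.72), Lypd1 (2.46), Cdr1 (-12.99), BC049635 (-8.25) and Klhl34 (-7.32), the first 3 being genes higher in PD013 libraries than in the others and the last 3 genes near 0 there.

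Changed-back genes in IP: the simulated covariance from shared tumor libraries was 6.414% of the observed, which argues against sharing as the whole cause, though sharing alone gave a correlation of -0.501 (observed -0.670) and opposite signs for 66.6% of genes (observed 76.5%). Other-cell RNA carried in the control and tumor IP libraries and less in the AZD IP libraries may account for part of the pattern: in the contrast of IP minus input between AZD and tumor, the highest median of the 7 other-cell lists was -1.73 and the lowest -2.07. The T cell list, not among the 7, had a median of -0.98 there with the replicate block (1 higher and 2 lower of 8). Astrocyte, oligodendrocyte and inhibitory-neuron genes were mostly lower in tumor IP already, so their fall with AZD was no change back. Difference between the library sets cannot be told apart from AZD, since 0 library sets hold both tumor and AZD IP libraries. Return of excitatory-neuron transcripts toward control stays open: in a set from AZD IP against input with IP libraries scaled to it, 65.79% of the 38 genes changed in tumor changed back, but that set was chosen on these libraries. Of those that changed back, 21 were higher in tumor and then lower, and 4 lower and then higher. On this scale 7 of the 676 genes of the set were lower in tumor. Scaling to the set takes out any fall shared by its genes, so it cannot show the return of such a fall.

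Genes low or high in PD013 alone: they number 32 (29 low there and 3 high). Of the 32, 29 have coordinates, and 23 of these (79.3%) overlap another gene, against 48.8% of other genes (Fisher's exact test, two-sided p = 0.00118, and 0.00507 for the low genes alone). Overlapping genes counted differently in the library sets may thus be the cause for some of them. Cdr1, Klhl34, Hipk4, Ell3, C130083M11Rik and Cd160 overlap no other gene in the coordinates used, so an overlap is not shown for these. Genes missing from those coordinates and a different use of strand were not tested, so a difference in counting stays open for them. Enrichment in IP RNA is argued against by 30 genes chosen in the same way on the control and tumor libraries alone, whose AZD input level was a median of 96.94% of their AZD IP level. Change with AZD is argued against as the whole cause by 79 genes chosen on the input libraries alone, of which 93.67% were over 8 times higher in control IP than in control input. No biological explanation was tested beyond these.

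Genes with a larger IP over input ratio in tumor: length by genomic span (introns included) is argued against as a general trend. The longest 10% of genes by span had a median log2 fold of 0.05. But 4 of the 8 genes lie among them, and the 8 had a median span of 153.89 kb, against 23.583 kb for all genes. Transcript length was not tested and stays open. A single tumor library pair is argued against for the genes still called higher without a tumor replicate (19, 6 and 3 without replicates 1, 2 and 3). Of these, 100% in each case were higher in the left-out tumor pair than in each control pair. A gene that rests on a single pair loses its call without that pair and leaves this check. The check therefore does not cover all 8 genes, and the control pairs were also used in the calls. RNA of tumor cells carried into the IP stays open for all 8. In 7 of them the lowest log2 IP over input in a tumor pair was 0.72, above the 0.48 that was the highest of 54 glioma-lineage and proliferation genes. But the 8 were picked from 16016 genes for a larger ratio in these same tumor libraries, and the 54 were not. Lying above the 54 therefore cannot decide it. Rgl2 lay at -0.99. A change in neurons stays open and was not tested.

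For each of the 13 results compared below, 1 of 10 splits of the libraries (the real one) gave as many genes; 10 splits are too few for a share under 0.1. The highest other count was 0 in each by edgeR, and DESeq2 was not run on the other splits. The real split called 776 genes for tumor IP against input, 5461 for control IP and 9245 for AZD IP. At an unadjusted p under 0.05 it gave 3222, 6943 and 9863, and the highest other split 2332, 609 and 382. Besides the real split, 3 splits part all pairs of IP and input; they gave 0 in edgeR and at most 37, 54 and 27 at that unadjusted p. In IP the real split called 7402 for tumor against control, 9229 for AZD against tumor and 5246 for AZD against control. Unadjusted it gave 8503, 9982 and 6825, and the highest other 293, 961 and 903. In input the same comparisons called 7461, 2646 and 5703, with 8639, 5043 and 7331 unadjusted and 898, 1984 and 351 in the highest other split. IP minus input called 11 for tumor and 5296 for AZD, with 528 and 7007 unadjusted and 158 and 273 in the highest other split. Among neuron-enriched genes 105 and 148 were called, with 134 and 172 unadjusted and 12 and 14 in the highest other split. For the genes changed back, 1 of 100 draws (the real one) gave 5597 and the highest other 1465. Each other draw mixed the conditions and the library sets within groups. The draws therefore show only that the groups differ, and cannot tell whether genes changed back beyond chance.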

How the results depend on the processing

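The sets from AZD IP, the set from the blocked tumor fit, the scaled libraries and camera with a block were chosen after seeing the data; the rest was planned. Of the alternative counts, 68 moved by over 1.5 times and 164 did not; the cause was not tested. Tumor IP against input (776 genes) gave 1728 with DESeq2, 451 with a mean of at least 5 CPM, 5433 with the replicate block and 2225 with all 18 libraries in a single fit. IP minus input gave, for tumor (11), 40 with DESeq2 and 67 with the replicate block, and for AZD (5296) 8025 with the block. Neuron-enriched genes between tumor and control (105) gave 394 with DESeq2, 68 at 5 CPM, 1500 with the block, 419 with all 18 libraries, 1397 with the set from control IP, 61 with the set enriched in all 3 conditions, 49 with a log2 fold above 1, 548 with the set from AZD IP above 1, 1487 with the blocked tumor set and 38 with IP libraries scaled to the AZD set. Between AZD and tumor (148) the same alternatives gave 506, 88, 1779, 557, 1695, 81, 63, 613 and 1766 up to the blocked tumor set, and 136 with scaled libraries. There 80 were higher and 68 lower in the main result, 370 and 136 with DESeq2, 25 and 38 with a log2 fold above 1, and 50 and 86 with scaled libraries. Between tumor and control 43 were higher and 62 lower in the main result, 27 and 22 with a log2 fold above 1, 31 and 7 with scaled libraries, and 8 and 540 with the set from AZD IP above 1. Genes changed back (5597) were 91 among neuron-enriched genes alone and 25 with scaled libraries.

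Lists called by camera went, with an estimated correlation, from 6 to 0 for tumor IP against input, 5 to 0 for control IP, 19 to 0 for AZD IP, 20 to 1 for tumor against control in IP, 18 to 1 for AZD against tumor in IP, 10 to 0 for AZD against control in IP, 20 to 1, 9 to 0 and 14 to 1 for the same comparisons in input, and 4 to 0 and 18 to 3 for IP minus input. Fry called 1, 0, 5 and 0 for tumor IP, control IP, AZD against tumor in input and IP minus input in tumor. Elsewhere fry called 20 lists for AZD IP against input and 15 for IP minus input in AZD. In IP it called 20 for tumor against control, 21 for AZD against tumor and 12 for AZD against control. In input it called 20 for tumor against control and 16 for AZD against control. The replicate block gave 13 for tumor IP against input.

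Leaving out a replicate gave 0 to 1755 for tumor IP against input (0 by edgeR without tumor replicate 2, with 1419 at an unadjusted p under 0.05 and 271 by DESeq2), 3134 to 4608 for control IP and 5929 to 9569 for AZD IP. It gave 5930 to 7906, 7936 to 9090 and 3429 to 6241 for tumor against control, AZD against tumor and AZD against control in IP, and 5679 to 7528, 1359 to 2598 and 3737 to 7289 in input. It gave 3 to 21 and 3498 to 5926 for IP minus input, 0 to 358 and 0 to 451 for neuron-enriched genes, and 4630 to 5908 for genes changed back. Where it left 2 libraries the edgeR fit was used.

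With the replicate block, list calls also appeared in tumor IP against input for excitatory neurons (adjusted p from 0.122 to 0.00375), microglia (0.013), glutamate synapses (0.016), GABA receptors (0.0349), channels (0.00154) and interferon (0.00723), each 0.921 with an estimated correlation, and matrix (0.000863, 0.662 with an estimated correlation). In IP minus input for tumor they appeared for proliferation (0.0153) and channels (0.0234), both 0.893 with an estimated correlation. At the preset correlation the paired fit changed no other list call in the 5 comparisons that pair IP with input. With an estimated correlation, in IP minus input for AZD, the microglial list went from 0.0345 to 0.058, and oligodendrocyte, proliferation, endothelial and matrix lists passed at 0.0489.

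Among the named genes, signs turned only for 3 that had not passed. Nrxn2 between tumor and control in IP (0.03) was at -0.02 with DESeq2 and with RLE size factors, and at -0.13 to 0.12 when replicates were left out. Asns between AZD and tumor in IP (-0.12) was at -0.27 to 0.14, and Per1 between AZD and tumor in input (0.11) at -0.16 to 0.37, when replicates were left out. Over all alternatives 93 calls of named genes were lost and 15 gained; of 38 genes named in tumor IP against input or IP minus input, 24 lost their call without tumor replicate 2 and 25 without tumor replicate 3.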

Other observations

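Some genes known to respond to glucocorticoids or FOXO factors were looked up in AZD input against tumor input, chosen after their values were seen and without a list test. Zbtb16 rose by 1.64 ± 0.14 (edgeR log2 fold, adjusted p = 5.2e-05), Tsc22d3, a glucocorticoid-induced leucine zipper gene, by 1.23 ± 0.13, Plin4 by 2.16 ± 0.27, Pdk4 by 1.46 ± 0.22 and Sesn1 by 0.73 ± 0.12. Fkbp5 (0.87 ± 0.37, adjusted p = 0.132), Klf9 (adjusted p = 0.0563) and Per1 (adjusted p = 0.781) did not pass. In IP, Zbtb16 (1.36 ± 0.13) and Sesn1 (1.03 ± 0.13) were higher, Pdk4 was lower (-1.17 ± 0.24) and Tsc22d3 did not pass (adjusted p = 0.344). Eif4ebp1, an mTOR substrate gene, was lower with AZD in input (-2.07 ± 0.38) and IP (-2.16 ± 0.35). The AZD libraries are a library set of their own, so drug and set cannot be told apart here.

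The small nucleolar RNA gene Snord15a and the Cajal-body RNA gene Scarna6 were lower in IP than in input in each condition, while Snord91a was higher in control (4.09 ± 0.38) and tumor (3.86 ± 0.39) but did not pass with AZD (adjusted p = 0.419). It was at 0.182 and 0.175 CPM in control and tumor input and 2.68 in AZD input, so it follows the PD013 set. Snord15a was at -4.96 ± 0.41 in control IP against input, -5.69 ± 0.55 in tumor and -4.27 ± 0.21 with AZD, and Scarna6 at -3.20 ± 0.30, -2.82 ± 0.40 and -3.49 ± 0.17.

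Activity genes were looked at after the values were seen, with IP libraries scaled to the 676 genes more than doubled in AZD IP over input, a set that took 13.9 to 15.7% of counts in control IP, 8.45 to 10.1% in tumor IP and 17.1 to 18.1% in AZD IP. On the main scale 8 of the 676 genes were higher and 540 lower in tumor than in control. Scaled to the set, 31 genes were higher and 7 lower in tumor than in control (38 in all). Fosb was at 3.18 ± 0.42, Ptgs2 at 2.81 ± 0.46, Dusp5 at 1.94 ± 0.25 and Bdnf at 1.22 ± 0.21, and with AZD against tumor Fosb was at -3.02 and Bdnf at -1.22. These genes and the set were chosen from the same libraries, so no test of activity genes is given, and no explanation was tested.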
